A study of Oryza sativa with 48 samples.

How the data were processed

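Leaves of 2 rice genotypes, M202 and its near-isogenic line M202(Sub1), were sampled as elongating and non-elongating leaves at day 0 and after 1, 3 and 6 days of complete submergence. Per the labels, each of the 16 groups had 3 independent biological replicates, and total RNA was sequenced in pairs of reads. The deposited values are raw counts per gene and library. The submitters' processing notes name STAR for alignment to the rice assembly IRGSP-1.0, featureCounts for counting and DESeq2, without versions. Even numbers made up 62.3 to 73.8% of the counts in each library, so both reads of a pair appear to have been counted singly, and the counts are then not independent reads. All 48 value columns were used.

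The table holds 37830 genes, of which 7430 had no count in any library. Totals lay between 4873142 and 10369501 counts per library (median 6854259.5). Genes with enough counts were kept with filterByExpr of edgeR (minimum count 10, minimum total 15), which left 21453 genes and at least 99.86% of the counts of each library. Libraries were scaled with TMM factors. Gene levels are given as counts scaled to the size of the library (CPM) with the SD over 3 libraries. The correlation of replicates lay between 0.9596 and 0.9809.

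Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) in 1 fit of all 16 groups, with 32 residual degrees of freedom, a common biological coefficient of variation of 0.152 and 13.2 prior degrees of freedom. All tests were two-sided, and p-values were adjusted over all tested genes by Benjamini and Hochberg, with a threshold of 0.05. The comparisons were 12 of a submerged day with day 0, 8 of M202(Sub1) with M202, 2 of the leaf types at day 0, 6 of the difference between the genotypes' responses and 2 of the difference between the leaf types' responses over the 3 submerged days together. Log2 changes carry the SE of the fit. Folds against a group without counts use a floor of 3 counts per library. Errors and floors cover counting error and the spread of these libraries only.

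The size of the response was scored per submerged library as the projection of its log2 CPM (prior count 2), minus the mean of its own genotype at day 0, onto the mean change of both genotypes, so that the genotypes average 1. Genotypes were compared with an exact two-sided permutation test, in which 3 libraries against 3 cannot give a p under 0.1. The libraries of a genotype share its day 0 mean, so the SD and this p leave out the spread at day 0.

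Gene lists were written from general knowledge before the data were examined, as 23 lists of 267 pairs of symbol and identifier, for fermentation, sucrose and starch breakdown, ethylene, the Sub1 locus with group VII ethylene response factors, gibberellin, abscisic acid, jasmonate, expansins, cellulose synthases of primary and secondary walls, chlorophyll synthesis, photosystems, the Calvin cycle, senescence with chlorophyll breakdown, growth-regulating factors, dehydration, heat shock, reactive oxygen, aquaporins, the clock, cell division, and markers of roots and of the shoot meristem. No table of IRGSP-1.0 identifiers with names was used. The RefSeq gene table used is of another assembly, so a pair was checked by its symbol lying on the chromosome of its identifier and in the same order. Of the 267 pairs, 266 had an identifier in the data, 172 were checked, 89 had a symbol outside the table, and 264 were used. Genes with close paralogues may share reads, which the counts do not resolve. The 20 lists with at least 3 tested members were tested with camera of limma 3.58.1, which asks whether a list ranks above or below other genes, at a preset correlation of 0.01 and with adjustment over the lists of a comparison. Counts of members are also given adjusted over the list alone. Of 560 tests 189 were called, and 101 of these hold with an estimated correlation.

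The rule for naming genes was also fixed before the data were examined. It takes genes marked in the lists, up to 5 genes per direction and comparison with the largest changes that carry a symbol and a mean CPM of at least 10, up to 4 members per list and comparison with the smallest adjusted p, and up to 10 genes called in all 8 genotype comparisons in the same direction. The share of these last genes on chromosome 9 was tested with a two-sided Fisher's exact test, with chromosomes read from the identifiers.

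The tests were tried on simulated data with 200 changed genes. Of genes changed 2-fold, 55.2% were recovered in a genotype comparison and 32.8% in a difference of responses, and of genes changed 4-fold 92.4% and 78.8%. A comparison without changed genes gave 0 calls. Alternatives were RLE and upper-quartile scaling, no filter, a replicate block, a fit of the groups compared alone, DESeq2 1.42.0 and each of the 48 libraries left out in turn. For the scores they were a prior count of 0.5 and the axis of M202 alone, and for the lists an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9 and tables assembled with pandas 2.3.3 (Python 3.11.15).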

Results

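Transcript abundance was measured by RNA sequencing in leaves of 2 rice genotypes held under water. M202 is a rice cultivar without the submergence tolerance gene SUB1A, and M202(Sub1) is the near-isogenic line that carries it. The fifth leaf, which was still elongating, was separated from the lower leaves, which had stopped elongating. Leaves were taken at day 0 and after 1, 3 and 6 days of complete submergence, which gave 16 groups of 3 independent biological replicates and 48 libraries. The comparisons ask how each leaf type of each genotype changed from day 0 under submergence, how the genotypes differed on each day, and whether genotype or leaf type changed the response. Total counts per library lay between 4873142 and 10369501 (median 6854259.5). Of 37830 genes, 21453 had enough counts to be tested.

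Libraries of the same group correlated across genes at 0.9596 to 0.9809 (median 0.9719), and the highest correlation between libraries of different groups was 0.9642. The first principal component, with 45.1% of the variance, separated the day 0 groups (group means -161 to -144) from all submerged groups (24.2 to 79.9). On the third component, with 9.75% of the variance, M202 lay above M202(Sub1) in each leaf type on each day. In non-elongating leaves on day 1, for example, the means were 6.46 ± 0.438 (SD, n = 3) and -66 ± 1 (SD, n = 3).

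Transcript abundance under water differed from day 0 for 49.9 to 56% of the tested genes, in both leaf types of both genotypes and on each day. Leaves kept in air until days 1, 3 and 6 were not among the groups compared, so these changes, called responses below, include those of leaf age and day of sampling. In non-elongating leaves of M202, 11255, 10991 and 11462 genes changed on days 1, 3 and 6, and in M202(Sub1) 12010, 11219 and 10934. In elongating leaves the counts were 11547, 10695 and 11482 in M202 and 11859, 11290 and 11435 in M202(Sub1). Genes that rose made up 48.5 to 52.1% of these calls. The changes of the genotypes, which were measured on separate libraries, correlated across genes at 0.831 to 0.872, and 98.2 to 99.3% of the genes called in both moved in the same direction. On day 1 in non-elongating leaves, 4490 genes rose in both genotypes, where independent lists would share 1519. The changes of the leaf types within a genotype correlated at 0.822 to 0.849. Genes are not independent replicates, so these correlations describe the profiles and carry no test.

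The genes of anaerobic fermentation rose under water, steeply by day 1 and less on later days. ADH1 (OS11G0210300), an alcohol dehydrogenase of ethanol fermentation, went in non-elongating leaves of M202 from 20.8 ± 3.72 CPM (counts scaled to the size of the library; SD, n = 3) at day 0 to 468 ± 43.1 on day 1, 231 ± 15.5 on day 3 and 51.9 ± 14.9 on day 6. In M202(Sub1) it went from 20.6 ± 2.86 to 1500 ± 59, 738 ± 76.8 and 313 ± 31.2 CPM. PDC1 (OS05G0469600), a pyruvate decarboxylase that makes the acetaldehyde used by alcohol dehydrogenase, had no counts at day 0 in non-elongating leaves. On day 1 it reached 47.7 ± 3.16 CPM in M202 and 69.9 ± 15.8 CPM in M202(Sub1), at least 97.7-fold and 149-fold above a floor of 3 counts per library. PPDKB (OS05G0405000), a pyruvate phosphate dikinase, fell by 2.39 ± 0.12 (log2, SE) in elongating leaves of M202 and by 2.69 ± 0.12 in those of M202(Sub1) on day 1. Of 9 tested members of the list, 7 rose and 2 fell on day 1 in non-elongating leaves of each genotype, and all 9 passed when adjusted over the list alone. The list ranked above other genes there (camera adjusted p = 1.38e-06 in M202 and 1.02e-07 in M202(Sub1)). By day 6 it no longer did so in M202 (adjusted p = 0.0645 in non-elongating and 0.226 in elongating leaves). In elongating leaves the calls in M202 on day 3 (0.0371) and in M202(Sub1) on day 6 (0.0192) were lost, with adjusted p = 0.082 and adjusted p = 0.0595 with an estimated correlation.

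Genes that release sugars moved in both directions. CIPK15 (OS11G0113700), a kinase that links oxygen deficiency to sugar starvation signalling, rose in all 12 comparisons with day 0. In elongating leaves of M202 it went from 4.98 ± 2.28 to 311 ± 3.05 CPM by day 3 (log2 change 6.01 ± 0.22, SE; n = 3). The sucrose synthase genes SUS2 (OS06G0194900) and SUS4 (OS03G0340500) rose in all 12 comparisons, by 1.59 to 2.26 and 1.97 to 3.46 log2 units. SUS1 (OS03G0401300) fell, for example by 3.12 ± 0.31 log2 units in elongating leaves of M202(Sub1) on day 1. Amy3D (OS08G0473900), an alpha amylase induced by sugar starvation, had no counts in M202 at day 0. It reached 8.02 ± 1.58 CPM on day 6 in non-elongating leaves of M202, at least 16.4-fold above the floor. The list of 13 tested members ranked above other genes once, in non-elongating leaves of M202 on day 3, with 7 members higher, 4 lower and 11 passing when adjusted over the list alone (camera adjusted p = 0.0225; adjusted p = 0.0816 with an estimated correlation).

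Genes of ethylene synthesis and signalling rose more often than they fell. ETR2 (OS04G0169100), an ethylene receptor, rose by 2.64 to 3.97 log2 units in all 12 comparisons. ACS5 (OS01G0192900), an enzyme that makes the ethylene precursor, had no counts at day 0 in any group and reached 22.6 ± 10.7 CPM in M202 and 24.7 ± 1.64 CPM in M202(Sub1) in non-elongating leaves on day 1, at least 46.2-fold and 52.7-fold above the floor. On that day 10 of 15 tested members rose and 3 fell in M202, and 14 passed when adjusted over the list alone. The list ranked above other genes in 11 of 12 comparisons, the exception being non-elongating leaves of M202 on day 6 (camera adjusted p = 0.0676). With an estimated correlation every one of the 11 calls was lost, with adjusted p between 0.0819 and 0.225.

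The ethylene response factors of group VII and the genes of the Sub1 locus rose together. In non-elongating leaves of M202, ERF66 (OS03G0183000) went from 17.7 ± 6.21 to 627 ± 9.17 CPM by day 1 and SUB1C (OS09G0287000) from 9.34 ± 2.93 to 453 ± 46.1 CPM (n = 3). SUB1B (OS09G0286600) rose by 2.48 to 4.49 and ERF67 (OS07G0674800) by 2.63 to 9.17 log2 units over the 12 comparisons. Of 6 members, 5 rose in each comparison, and the list ranked above other genes in all 12 (camera adjusted p from 2.78e-14 to 1.67e-06), also with an estimated correlation (adjusted p at most 0.00186). The pairing of these 4 names with their identifiers was written before the data were examined and was not checked against any table here. SUB1A itself was not analysed here.

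Genes of abscisic acid synthesis, breakdown and signalling fell as a list in every comparison. ZEP1 (OS04G0448900), the zeaxanthin epoxidase of abscisic acid synthesis, went in non-elongating leaves of M202 from 1860 ± 137 to 204 ± 20.2 CPM by day 1 (n = 3), and bZIP23 (OS02G0766700), a transcription factor of the abscisic acid response, from 84.6 ± 18.5 to 15.1 ± 2.56 CPM. ABA8ox1 (OS02G0703600), an enzyme that breaks abscisic acid down, rose there in M202(Sub1), by 3.08 ± 0.69 log2 units (SE). The list also holds the breakdown enzymes ABA8ox2 and ABA8ox3, so its fall does not separate synthesis from breakdown. In M202, 8 of 9 tested members fell and 1 rose on that day, and all 9 passed when adjusted over the list alone. The list ranked below other genes in all 12 comparisons (camera adjusted p from 5.21e-06 to 0.00281), also with an estimated correlation (at most 0.0131). Gibberellin genes as a list were not called in any of the 12 (camera adjusted p from 0.11 to 0.639). Within it GA20ox2_SD1 (OS01G0883800), a gibberellin 20-oxidase, rose in elongating leaves of M202 from 0.735 ± 0.932 to 49.4 ± 3.74 CPM by day 1 and in M202(Sub1) from 2.15 ± 0.65 to 60.6 ± 11.9 CPM.

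Cellulose synthase genes of primary walls fell in elongating leaves. CESA1 (OS05G0176100) fell there from 1430 ± 84 to 221 ± 2.16 CPM in M202 and from 1240 ± 138 to 134 ± 20.8 CPM in M202(Sub1) by day 1 (n = 3). All 6 members fell in M202(Sub1) on each day, with median log2 changes of -2.53, -1.95 and -1.88, and passed when adjusted over the list alone (camera adjusted p = 1.35e-09, 1.87e-08 and 4.39e-07). Calls of this list also held with an estimated correlation in those 3 comparisons and in M202 on day 1 (adjusted p at most 0.0241), while in elongating leaves of M202 on days 3 and 6 they did not (adjusted p = 0.0518 and 0.052 with an estimated correlation). Of 3 cellulose synthase genes of secondary walls, 2 were tested, and both fell in elongating leaves of M202(Sub1) on each day. Expansins, which loosen cell walls, ranked above other genes in 1 of the 12 comparisons, elongating leaves of M202 on day 3, where 9 of 11 rose and 1 fell (camera adjusted p = 0.0371; adjusted p = 0.108 with an estimated correlation). EXPA4 (OS05G0477600) rose there by 2.68 ± 0.35 log2 units.

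Photosynthetic genes fell. All 10 genes of the Calvin cycle list fell in elongating leaves of M202(Sub1) on each day, with median log2 changes of -2.21, -1.85 and -1.77. RCA (OS11G0707000), rubisco activase, went there from 8960 ± 1460 to 1240 ± 215 CPM by day 1 (n = 3). This list ranked below other genes in all 12 comparisons (camera adjusted p from 4.05e-07 to 0.0024), and with an estimated correlation in all but elongating leaves of M202 on day 3 (adjusted p = 0.0518 with an estimated correlation). Genes of the photosystems and light-harvesting antennae fell in elongating leaves, where 20 of 22 were lower in each genotype by day 6, with median log2 changes of -1.71 in M202 and -1.53 in M202(Sub1). The camera calls there (3.49e-08 and 2.66e-06) were lost, with adjusted p = 0.172 and adjusted p = 0.153 with an estimated correlation. Of these lists 2 of 10 Calvin cycle and 3 of 22 photosystem members had a name checked against the gene table.

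The list of senescence and chlorophyll breakdown rose in M202. In elongating leaves on day 6, 8 of 12 members rose and 1 fell, and 10 passed when adjusted over the list alone (camera adjusted p = 0.000134; 0.00404 with an estimated correlation). SGR (OS09G0532000), the stay-green gene whose product starts chlorophyll breakdown, went there from 11.4 ± 1.42 to 89.7 ± 17.5 CPM (n = 3), and GDH2 (OS04G0543900), a glutamate dehydrogenase, from 28.8 ± 6.02 to 94.1 ± 10.7 CPM. In non-elongating leaves of M202 the list was called on days 1, 3 and 6 (0.0293, 0.00232 and 0.0183), with adjusted p = 0.0777, 0.0112 and 0.0621 with an estimated correlation. In elongating leaves of M202 on day 3 the call (0.0364) had adjusted p = 0.082 with an estimated correlation. With the 7 checked members alone the submergence calls of this list were lost (adjusted p = 0.129 to 0.975 in M202). In M202(Sub1) it was not called in any of the 6 comparisons (camera adjusted p from 0.148 to 0.901).

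PIP2_7 (OS09G0541000), an aquaporin of the plasma membrane, went in elongating leaves of M202 from 250 ± 42.7 to 11.6 ± 2.41 CPM by day 1, and TIP2_2 (OS06G0336200), an aquaporin of the vacuole, rose from 33.6 ± 3.34 to 128 ± 11.7 CPM. In non-elongating leaves 8 of 10 aquaporins fell on day 1 in each genotype (camera adjusted p = 0.00424 in M202 and 0.000234 in M202(Sub1); 0.0437 and 0.00809 with an estimated correlation). SALT (OS01G0348900), a stress-induced lectin of the dehydration list, rose in all 12 comparisons by 0.88 to 5.09 log2 units. That list was called once, in elongating leaves of M202(Sub1) on day 6 (0.047; adjusted p = 0.0947 with an estimated correlation). The clock, cell division, heat shock, jasmonate and growth-regulating factor lists were not called in any of the 12 comparisons (lowest camera adjusted p 0.142, 0.113, 0.217, 0.0929 and 0.0659). PCNA (OS02G0805200), a clamp of DNA replication, rose in elongating leaves, by 2.09 ± 0.31 log2 units in M202 on day 1. Of 7 root markers 2 passed the filter, and neither rose in any of the 12 comparisons. Genes that handle reactive oxygen fell as a list in elongating leaves on day 6, 10 of 15 in each genotype (0.00453 in M202 and 0.00561 in M202(Sub1); adjusted p = 0.172 and adjusted p = 0.13 with an estimated correlation). Chlorophyll synthesis genes fell there too, 11 of 12 in M202 and 10 of 12 in M202(Sub1) (0.00158 and 0.00637; adjusted p = 0.172 and adjusted p = 0.153 with an estimated correlation). None of 3 shoot meristem markers passed it.

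Before submergence the genotypes differed in 588 genes of non-elongating leaves (257 higher and 331 lower in M202(Sub1)) and 1138 genes of elongating leaves (678 higher and 460 lower). SUB1B was lower in M202(Sub1) in both leaf types, at 11 ± 3.56 against 27.3 ± 4.09 CPM in non-elongating and 5.7 ± 3.54 against 19.4 ± 1.42 CPM in elongating leaves (n = 3). The differences in the leaf types, measured on separate libraries, overlapped: 149 genes were higher in M202(Sub1) in both, where independent lists would share 8.122, and 204 were lower in both against 7.097. The fermentation list did not differ at day 0 (camera adjusted p = 0.943 and 0.831). In elongating leaves the photosystem list was higher in M202(Sub1), with 3 of 22 members called (0.000805; adjusted p = 0.349 with an estimated correlation). Among these is LHCB1_CAB1R (OS09G0346500), which was higher in M202(Sub1) in all 8 genotype comparisons. It lies in a stretch of 50 tested genes on chromosome 9 with 13 genes called in all 8. Without replicate 1 of M202 in elongating leaves the count there was 517, and without replicates 1 and 3 of M202(Sub1) in turn it was 697 and 665. Fitted on the groups compared alone, non-elongating leaves gave 386 genes.

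Under water the genotypes differed in more genes. In non-elongating leaves 3226, 2963 and 3284 genes differed on days 1, 3 and 6, of which 1276, 1274 and 1539 were higher in M202(Sub1). In elongating leaves the counts were 4358, 3150 and 4367, with 1880, 1358 and 2205 higher. The differences in the leaf types correlated across genes at 0.612, 0.645 and 0.654 on these days. Of the genes called in both leaf types 97.6 to 98.5% had the same direction. The count of non-elongating leaves on day 6 was 1336 in a fit of the groups compared alone. Replicate 2 of M202 in that group had the 2 lowest correlations of all replicates (0.9596 and 0.963), and its 10 most abundant genes held 27.5% of its counts.

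**Figure D1:**
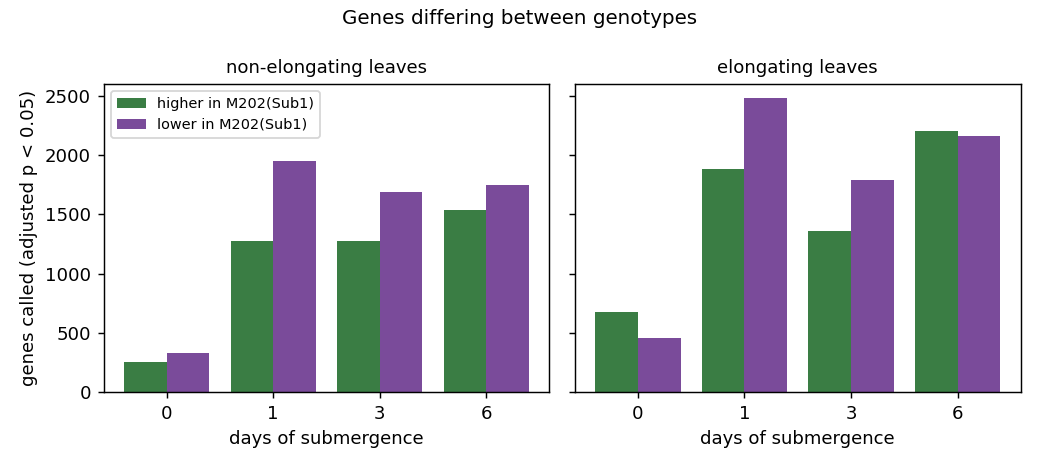
Number of genes that differed between M202(Sub1) and M202 in each leaf type (vertical axis, genes called) on days 0, 1, 3 and 6 of submergence (horizontal axis). Genes higher and genes lower in M202(Sub1) are drawn as separate bars side by side. The counts of both directions together run from 588 in non-elongating leaves at day 0 to 4367 in elongating leaves on day 6.

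Fermentation genes were higher in M202(Sub1) than in M202 on each day under water. ADH1 was higher by 1.68 ± 0.15, 1.68 ± 0.15 and 2.59 ± 0.15 log2 units (SE) in non-elongating leaves on days 1, 3 and 6, and by 1.42 ± 0.15, 2.04 ± 0.15 and 2.77 ± 0.16 in elongating leaves. ADH2 (OS11G0210500), another alcohol dehydrogenase, stood at 57.7 ± 6.3 against 5.1 ± 0.3 CPM in elongating leaves on day 1, and PDC1 at 63.8 ± 12.2 against 7.27 ± 1.91 CPM (n = 3). PPDKB was lower in M202(Sub1), by -1.22 ± 0.11 log2 units in non-elongating leaves on day 3. In elongating leaves on day 3, 5 of 9 members were higher and 2 lower, and 8 passed when adjusted over the list alone. The list was called on all 3 days (camera adjusted p = 0.000369, 0.000954 and 1.97e-05 in non-elongating and 1.57e-07, 1.39e-06 and 0.00969 in elongating leaves), also with an estimated correlation (at most 0.0271).

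The response of ADH1 itself differed between the genotypes. It rose by 1.70 ± 0.22, 1.70 ± 0.22 and 2.60 ± 0.23 log2 units more in M202(Sub1) than in M202 in non-elongating leaves on days 1, 3 and 6, and by 1.09 ± 0.23, 1.71 ± 0.23 and 2.44 ± 0.24 more in elongating leaves (adjusted p from 2.1e-11 to 0.00088). The fermentation list as a whole showed no call in this difference of responses (camera adjusted p from 0.0925 to 0.888). On day 6 in elongating leaves 1 of its 9 members changed relatively higher and 1 relatively lower in M202(Sub1). ADH1 and ADH2 lie on chromosome 11, in the stretch of 50 tested genes from OS11G0208000 to OS11G0226400. It held 0 genes called in all 8 genotype comparisons, and the stretch before it held 4. Whether the differences of ADH1 and ADH2 come from sequence at that position, such as donor sequence, was not tested.

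CIPK15 was lower in M202(Sub1) on each day under water, for example at 54.7 ± 4.54 against 311 ± 3.05 CPM in elongating leaves on day 3 (n = 3). Its response there was smaller by -2.09 ± 0.34 log2 units (adjusted p = 2.6e-05). CIPK15 lies in a stretch of 50 tested genes on chromosome 11 (OS11G0112200 to OS11G0124300) with 5 genes called in all 8 genotype comparisons. Whether its difference comes from sequence at that position, such as donor sequence, was not tested. Amy3D was at 1.45 ± 0.361 against 8.02 ± 1.58 CPM in non-elongating leaves on day 6 (adjusted p = 0.0013). TPP1 (OS02G0661100), a trehalose phosphate phosphatase, was higher in M202(Sub1), at 284 ± 107 against 52.5 ± 16.3 CPM in elongating leaves on day 6, and its change from day 0 there was higher by 2.16 ± 0.32 log2 units. The sugar list was called in 1 of 6 genotype comparisons under water, lower in non-elongating leaves on day 3 with 2 members higher and 3 lower (camera adjusted p = 0.0451; adjusted p = 0.143 with an estimated correlation), and in none of the differences of responses (0.259 to 0.993).

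Chlorophyll breakdown and senescence genes were lower in M202(Sub1) under water. In non-elongating leaves SGR was at 19.5 ± 4.59 CPM in M202(Sub1) and 126 ± 5.53 CPM in M202 on day 3 (n = 3), NYC1 (OS01G0227100), a chlorophyll b reductase, at 92.8 ± 11.6 and 260 ± 8.33 CPM, and GDH2 at 18.3 ± 1.57 and 68.4 ± 0.433 CPM. Of 12 members 7 were lower and none higher on that day, and 7 passed when adjusted over the list alone. The list was called in non-elongating leaves on days 1, 3 and 6 (camera adjusted p = 1.39e-05, 3.99e-09 and 4.31e-06) and in elongating leaves on day 6 (1.89e-06), also with an estimated correlation and with the checked members alone (at most 0.00104). In elongating leaves on day 3 the call (0.0248) had adjusted p = 0.0911 with an estimated correlation. At day 0 the list did not differ (0.984 and 0.506). The change of SGR from day 0 differed between M202(Sub1) and M202 by -3.61 ± 0.37, -3.39 ± 0.34 and -3.66 ± 0.34 log2 units in non-elongating leaves on days 1, 3 and 6. These values include any difference of SGR between the genotypes at day 0 as well as that under water. On day 3 SGR fell by 3.15 ± 0.26 log2 units in M202(Sub1) and was not called changed in M202 (adjusted p = 0.39). The list's changes were relatively lower in M202(Sub1) there too (3.55e-05, 1.61e-07 and 3.24e-05; at most 0.00184 with an estimated correlation).

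**Figure D2:**
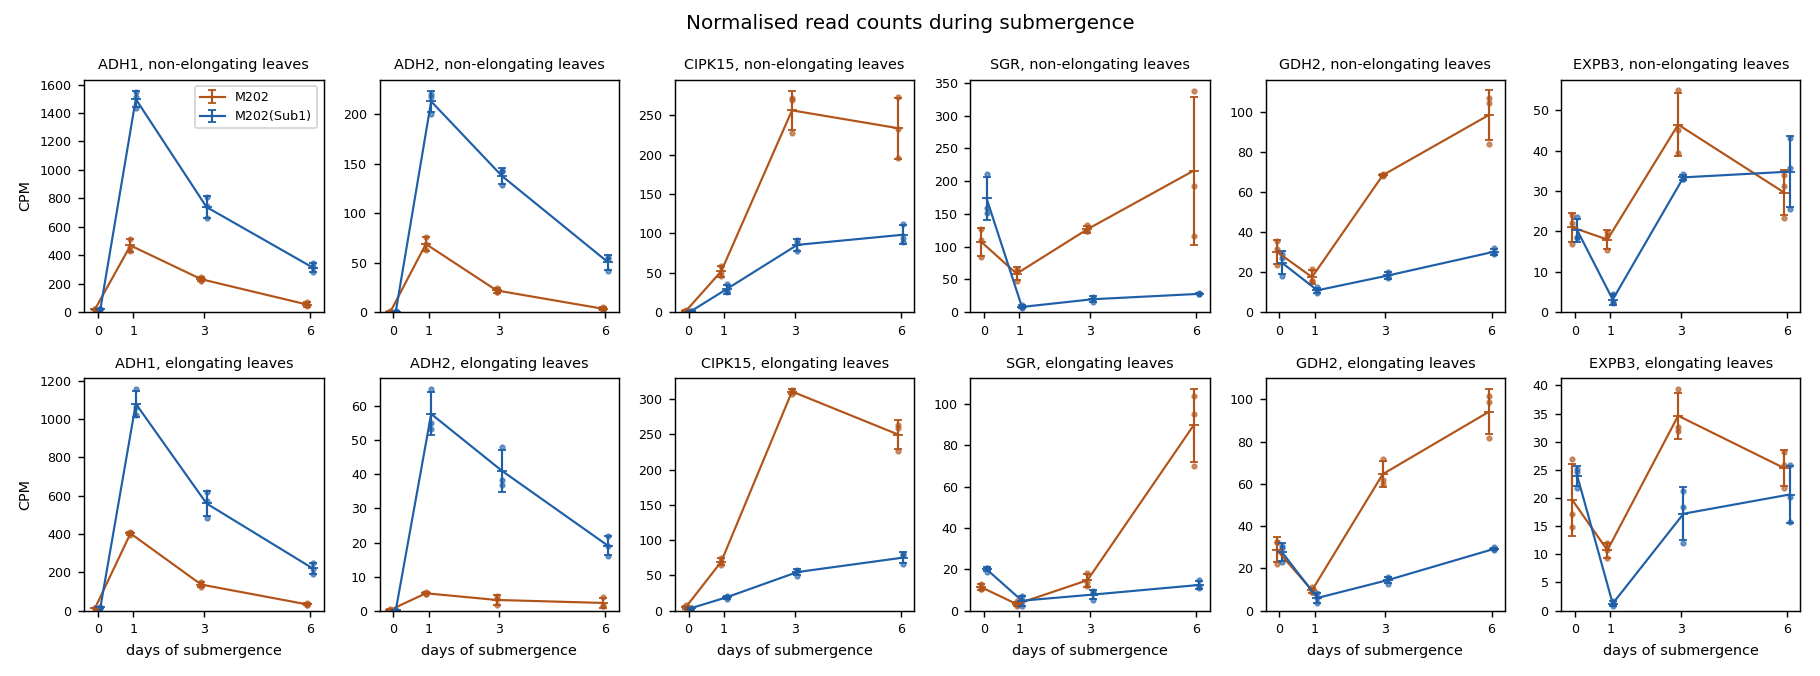
Normalised abundance (CPM, vertical axes) of ADH1, ADH2, CIPK15, SGR, GDH2 and EXPB3 against days of submergence (horizontal axes) in each genotype and leaf type, as means of 3 libraries with SD bars and the single libraries as points. ADH1 and ADH2 stood higher and CIPK15 and GDH2 lower in M202(Sub1) on day 3, when ADH1 was at 738 against 231 CPM in non-elongating leaves.

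Genes of wall extension were lower in M202(Sub1) on day 1. EXPB3 (OS10G0555900), a beta expansin, was at 1.25 ± 0.432 against 10.7 ± 1.36 CPM in elongating leaves and at 3.08 ± 1.31 against 18 ± 2.32 CPM in non-elongating leaves (n = 3). EXPA4 was at 2.21 ± 0.551 against 14.3 ± 0.275 CPM in elongating leaves. On that day 7 of 11 expansins were lower in non-elongating and 5 of 11 in elongating leaves, with none higher, and 8 and 6 passed when adjusted over the list alone (camera adjusted p = 9.82e-07 and 1.87e-05; 0.000608 and 0.0019 with an estimated correlation). The responses differed on day 1 in both leaf types (1.17e-05 and 6.96e-10; 0.00135 and 5.83e-05 with an estimated correlation). In elongating leaves they also differed on day 3 (camera adjusted p = 0.00738) and on day 6 (0.0497, a call lost with an estimated correlation). EXPB4 (OS10G0556100) rose in elongating leaves of M202 by 1.67 ± 0.39 and fell by 2.28 ± 0.48 log2 units in those of M202(Sub1), which was chosen after its values were seen. The level of the list on day 6 did not differ between the genotypes in either leaf type (0.35 and 0.578). All 6 primary wall cellulose synthases were lower in M202(Sub1) on day 1 in both leaf types, with median log2 differences of -0.72 and -0.72. The call held in non-elongating leaves (1.05e-05; 0.0491 with an estimated correlation) and was lost in elongating leaves (7.32e-05; adjusted p = 0.123 with an estimated correlation).

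The genes for chlorophyll synthesis responded differently in elongating leaves on day 1. CHLH (OS03G0323200), a subunit of magnesium chelatase, fell from 4620 ± 399 to 1710 ± 110 CPM in M202(Sub1) and from 3660 ± 360 to 2480 ± 82.3 CPM in M202 (n = 3), a difference of -0.87 ± 0.18 log2 units (adjusted p = 0.00062). Of 12 members 10 responded lower in M202(Sub1), the median difference was -0.90 log2 units, and 10 passed when adjusted over the list alone (camera adjusted p = 1.47e-08; 0.0218 with an estimated correlation). Of 22 photosystem genes 13 responded lower there and none higher (6.96e-10; adjusted p = 0.132 with an estimated correlation). By day 6 in elongating leaves 12 photosystem genes were higher in M202(Sub1) and none lower (1.71e-05; adjusted p = 0.237 with an estimated correlation). They include LHCB1_CAB1R, which was higher at day 0 as well. The Calvin cycle list was higher there as well, with 6 of 10 members called (0.0133; adjusted p = 0.104 with an estimated correlation).

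Further groups differed between the genotypes under water. GRF7 (OS12G0484900), a growth-regulating factor, was at 24.4 ± 2.32 against 2.63 ± 0.752 CPM in non-elongating leaves on day 6 (n = 3). Of 4 tested growth-regulating factors 2 were higher there and none lower, and 3 passed when adjusted over the list alone (camera adjusted p = 0.00604; 0.0132 with an estimated correlation). The dehydration list was higher in elongating leaves on day 6, with 5 of 10 members higher and 1 lower (0.0122; 0.0275 with an estimated correlation). SALT stood there at 409 ± 70.6 against 90.3 ± 3.05 CPM, while NAC5 (OS11G0184900), a stress-related transcription factor, was lower at 3.77 ± 1.13 against 25.8 ± 7.21 CPM. NAC5 lies on chromosome 11 in a stretch of 50 tested genes with 4 called in all 8 genotype comparisons. Abscisic acid genes were higher on day 6 in both leaf types, 3 and 4 of 9 members with none lower (0.00887 and 0.0155; 0.0163 and 0.0275 with an estimated correlation). Among genes that handle reactive oxygen, CATA (OS02G0115700), a catalase, was at 10.1 ± 1.97 against 167 ± 16.8 CPM in non-elongating leaves on day 3. SODA (OS05G0323900), a superoxide dismutase, was higher in M202(Sub1), at 117 ± 3.49 against 58.3 ± 8.4 CPM in elongating leaves on day 1. That list was called lower in non-elongating leaves on day 3 with 1 member higher and 5 of 15 lower (0.00815; adjusted p = 0.153 with an estimated correlation). The clock gene LHY (OS08G0157600) was at 699 ± 24.8 against 1620 ± 44 CPM in elongating leaves on day 1. Jasmonate genes were higher in elongating leaves on day 6, 4 of 11 with none lower (0.0331; adjusted p = 0.167 with an estimated correlation). Clock genes were higher in non-elongating leaves on day 1, 5 of 8 with 1 lower (0.0472; adjusted p = 0.062 with an estimated correlation), and 4 of 10 aquaporins were lower there (0.0415; adjusted p = 0.115 with an estimated correlation). The gibberellin, heat shock and cell division lists were not called in any genotype comparison (lowest camera adjusted p 0.061, 0.052 and 0.0614).

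The Sub1 locus and group VII list changed relatively higher in M202(Sub1). SUB1B rose by 1.73 ± 0.25 and 1.62 ± 0.27 log2 units more in non-elongating and elongating leaves on day 1, from the lower level at day 0 (adjusted p = 5.2e-06 and 3.7e-05). On day 1 its levels were 248 ± 23.5 against 185 ± 8.75 CPM in non-elongating leaves (adjusted p = 0.062; n = 3). ERF67 was at 151 ± 35.8 against 37.6 ± 5.27 CPM in elongating leaves on day 1. The list's responses were called in all 6 comparisons (camera adjusted p = 0.000138, 0.00321 and 0.000203 in non-elongating and 0.0148, 0.00055 and 0.00144 in elongating leaves). The calls in non-elongating leaves on day 3 and in elongating leaves on day 1 were lost, with adjusted p = 0.0542 and adjusted p = 0.114 with an estimated correlation. By gene, the response differed in 6 comparisons for SUB1B, 3 for SUB1C, 2 for ERF66 and 1 for ERF67. SUB1B and SUB1C belong to the locus in which the genotypes differ. Donor sequence, or reads shared with SUB1A, may therefore affect their counts, which was not tested.

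Across all genes the response to submergence differed between the genotypes for 1173, 1222 and 1371 genes in non-elongating leaves on days 1, 3 and 6, of which 409, 476 and 615 were relatively higher in M202(Sub1). In elongating leaves 2402, 1207 and 1371 genes differed, of which 873, 364 and 575 were relatively higher. On day 1 in non-elongating leaves, 876 of the 1173 genes had fitted changes of the same sign in both genotypes, whether or not each change was called, 725 of them with the larger fitted change in M202(Sub1) and 151 with the larger in M202. In elongating leaves the corresponding genes numbered 1563, 1066 and 497. On day 3 the larger change was in M202(Sub1) for 498 and in M202 for 312 genes of non-elongating leaves, and for 572 and 257 genes of elongating leaves. By day 6 these were 514 and 402, and 470 and 467. The count for non-elongating leaves on day 6 was 486 in a fit of the groups compared alone, with the same M202 libraries of day 6.

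The overall size of the response was scored per library along the mean change of both genotypes, where the mean of the genotypes is 1. On day 1 the score was 1.05 ± 0.0039 in M202(Sub1) and 0.953 ± 0.0071 in M202 in non-elongating leaves (SD of the submerged libraries, n = 3, which leaves out the spread at day 0), and 1.05 ± 0.016 and 0.954 ± 0.0061 in elongating leaves. The difference, M202(Sub1) minus M202, was 0.0948, 0.031 and 0.0131 on days 1, 3 and 6 in non-elongating leaves and 0.0923, 0.0639 and 0.0306 in elongating leaves. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 allow, in all comparisons but non-elongating leaves on day 6 (0.2). With 1 library left out in turn they ranged from 0.0741 to 0.104, 0.00891 to 0.043 and -0.00572 to 0.0248 in non-elongating leaves and from 0.0783 to 0.108, 0.0523 to 0.0752 and 0.0125 to 0.0399 in elongating leaves, so the direction in non-elongating leaves on day 6 is not settled. An axis drawn from one genotype favours that genotype by construction. On that of M202 the differences were -0.0117, -0.0809 and -0.112 in non-elongating and -0.0585, -0.0653 and -0.0856 in elongating leaves, and on that of M202(Sub1), chosen after the data were seen, 0.175, 0.133 and 0.133, and 0.207, 0.171 and 0.137.

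**Figure D3:**
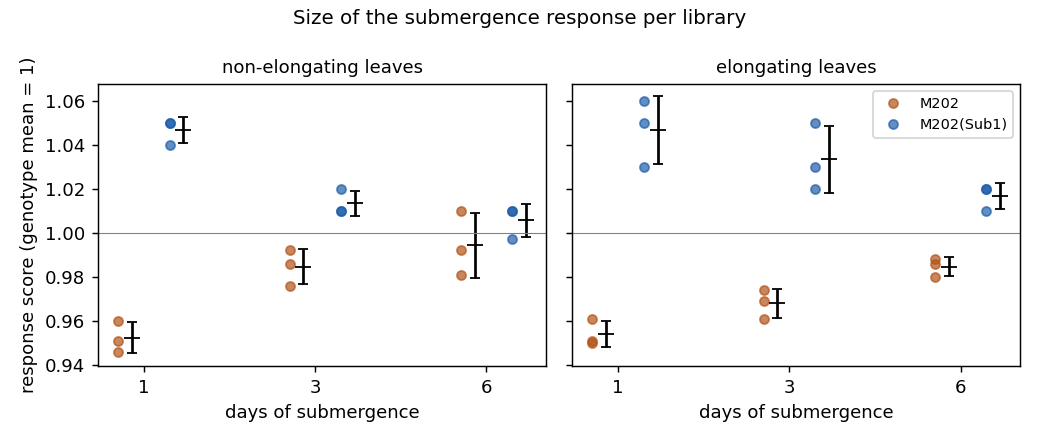
Response size score of each submerged library (vertical axis, units of the mean change of both genotypes) on days 1, 3 and 6 (horizontal axis) in each leaf type, with the mean of 3 libraries per genotype. On day 1 the means were 1.05 in M202(Sub1) and 0.953 in M202 in non-elongating leaves.

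The genes that differed between the genotypes in every comparison were clustered on a few chromosomes. In all 8 comparisons 190 genes were called in one direction, 57 higher and 133 lower in M202(Sub1). OS08G0208400, for which no name was used here, ranged from 24.3 to 1010 CPM over the 24 libraries of M202(Sub1) and from 0 to 0.319 CPM over the 24 of M202. OS09G0355400 ranged from 0 to 0.593 CPM in M202(Sub1) and from 148 to 430 CPM in M202, and OS12G0254400 from 0 to 0.387 against 88.4 to 185 CPM. Chromosome 9, which holds the Sub1 locus, had 40 of these genes among its 1174 tested, against 150 among 20279 on the other chromosomes (odds ratio 4.73, two-sided Fisher's exact p = 1.29e-13). Linked genes are not independent, so this p is a description. Chromosome 12 had 67 among 1205 tested, chromosome 11 had 36 among 1206 and chromosome 6 had 17 among 1738. On chromosome 9 the stretch of 50 tested genes with the identifiers of SUB1B and SUB1C held 1 of them. The stretches that follow it held 6, 13 and 16.

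**Figure D4:**
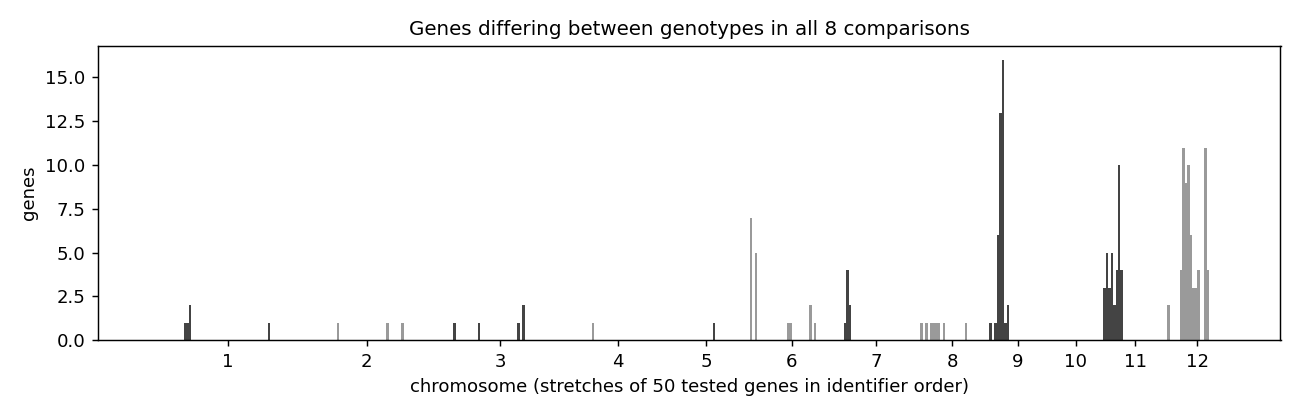
Genes called in one direction in all 8 genotype comparisons (vertical axis, number per stretch of 50 tested genes) along the 12 chromosomes (horizontal axis, order of the gene identifiers). The 13 stretches with at least 5 such genes held 114 of the 190 genes.

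Before submergence the leaf types differed in 6329 genes of M202 (2977 higher and 3352 lower in elongating leaves) and 6397 genes of M202(Sub1) (3074 higher and 3323 lower). Genes that build the photosynthetic apparatus were higher in elongating leaves. All 12 chlorophyll synthesis genes were higher in M202(Sub1) and 11 in M202, with median log2 differences of 1.46 and 1.31 (camera adjusted p = 2.75e-18 and 4.96e-12; 0.000394 and 0.00312 with an estimated correlation). CHLH was at 3660 ± 360 CPM in elongating and 1330 ± 328 CPM in non-elongating leaves of M202 (n = 3). Of 22 photosystem genes 19 were higher in M202 and 20 in M202(Sub1), with 1 lower in each (0.0301 and 0.0136 with an estimated correlation), and 21 and 22 passed when adjusted over the list alone. Primary wall cellulose synthases were higher too, 5 of 6 in M202 and 6 of 6 in M202(Sub1) (0.0478 and 0.0136 with an estimated correlation). Senescence genes were lower in elongating leaves, 7 and 6 of 12 with 1 higher in each (2.43e-06 and 7.93e-06; 0.000944 and 0.000914 with an estimated correlation). SGR was at 11.4 ± 1.42 against 107 ± 21.7 CPM in M202. Gibberellin genes were lower in both genotypes (0.0471 and 0.0347; 0.0478 and 0.0434 with an estimated correlation), among them GA20ox2_SD1 at 0.735 ± 0.932 against 12.3 ± 3.63 CPM in M202.

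The response to submergence differed between the leaf types for 5988 genes in M202 and 4508 genes in M202(Sub1), as tested over days 1, 3 and 6 together. ZEP1 was one of them in M202 (F = 46.8, adjusted p = 2.8e-11), as it fell by 3.19 ± 0.13 log2 units in non-elongating and by 1.30 ± 0.12 in elongating leaves on day 1. CATA was another (F = 48.3, adjusted p = 1.8e-11). On day 3 it rose by 0.85 ± 0.18 log2 units in non-elongating leaves of M202 and fell by 1.57 ± 0.18 in elongating leaves, which was chosen after its values were seen. In M202(Sub1), CESA1 fell by 2.86 ± 0.13 in non-elongating and 3.21 ± 0.13 log2 units in elongating leaves on day 1, and by 1.32 ± 0.12 and 2.81 ± 0.13 on day 3 (F = 29.2, adjusted p = 1.4e-08).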

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

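The tests of the senescence list against the sequence of the donor and without scaling factors, the axis of M202(Sub1), the jackknife, and the shift of all genes, were tests chosen only after the result was seen. The results below stand out because a response differed between groups by the test of the difference itself (edgeR quasi-likelihood, adjusted by Benjamini and Hochberg).

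The response to submergence differed between the genotypes for 1173, 1222 and 1371 genes in non-elongating leaves on days 1, 3 and 6 and for 2402, 1207 and 1371 genes in elongating leaves. It differed between the leaf types for 5988 genes in M202 and 4508 in M202(Sub1). Each of these was refitted on its own groups under 100 regroupings of the libraries within a day. In non-elongating leaves the real grouping gave 979, 1065 and 486 genes, and the highest other 2115, 1248 and 428. In elongating leaves it gave 2601, 1078 and 1609, and the highest other 1869, 2588 and 2445. For the leaf types it gave 5230 in M202 and 4697 in M202(Sub1), and the highest other 4547 and 3060. Counting the real one, 4, 2 and 1 groupings gave as many in non-elongating leaves and 1, 2 and 3 in elongating leaves. For the leaf types 1 grouping did so in each genotype. These are shares under 0.05 for all 8. The regroupings mix genotypes, or leaf types, that differ within a day. A small share can thus arise without a difference of responses, and it does not exclude chance. The groupings with 2115 and 2588 genes exchanged the genotypes of all 3 libraries per genotype on one day, which turns the difference of responses into a sum of genotype differences, a structure of the samples. The other 5 that gave more than the real one exchanged most of one day: all 3 of day 1 and 1 of day 0 (1140 and 1190, non-elongating leaves on day 1), or 2 of day 0 and none later (1248, non-elongating leaves on day 3; 2445 and 1855, elongating leaves on day 6).

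The comparisons of 3 libraries with 3 have 10 splits, too few for a share under 0.05, and the value was 1 split, the real one, for each. Real counts for days 1, 3 and 6 against day 0 were 10299, 9883 and 8739 in non-elongating leaves of M202, 10890, 10186 and 9390 in those of M202(Sub1), 10621, 9396 and 10393 in elongating leaves of M202, and 11244, 10406 and 11410 in those of M202(Sub1). For the genotypes on days 0, 1, 3 and 6 they were 386, 3877, 3525 and 1336 in non-elongating and 822, 5033, 2805 and 5433 in elongating leaves. For the leaf types at day 0 they were 4912 in M202 and 6024 in M202(Sub1). The highest other split gave 0 genes with edgeR in every one of these 22 comparisons.

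The difference of responses is the log2 change in M202(Sub1) minus that in M202, so a positive value is a larger rise or a smaller fall in M202(Sub1), or a rise there against a fall in M202. It was 2.60 for ADH1 and 3.99 for ADH2 in non-elongating leaves on day 6, 1.60 for SUS1 there, and 2.16 for TPP1 in elongating leaves on day 6. It was 1.90 for SUB1B in elongating leaves on day 3, 1.91 for SUB1C in non-elongating leaves on day 1, 1.29 for ERF66 in non-elongating leaves on day 6 and 4.23 for ERF67 in elongating leaves on day 6. EIL1 (OS03G0324300), a transcription factor of the ethylene response, had 0.668 in elongating leaves on day 6, and bZIP23 had 1.03 there on day 1. DREB1C (OS06G0127100), a transcription factor of cold and drought responses, had 4.82 and SALT 1.87 in elongating leaves on day 6. The stretch of 50 tested genes with DREB1C on chromosome 6 held 0 genes called in all 8 genotype comparisons. The stretches on either side held 7 and 5, and an effect of sequence at that position was not tested. P5CS1 (OS05G0455500), an enzyme of proline synthesis, had 1.21 in non-elongating leaves on day 3, SODA 1.02 in elongating leaves on day 3, and GI (OS01G0182600), a clock gene, 0.694 in non-elongating leaves on day 1. GRF7 differed in elongating leaves on day 6 with adjusted p = 0.0046. At least 1 of the groups compared held at most 3 counts in total, so no size is given. The stretch of 50 tested genes with GRF7 on chromosome 12 held 0 genes called in all 8 genotype comparisons, and the one before it 4.

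The difference was negative, a smaller rise or a larger fall in M202(Sub1) or a fall there against a rise in M202, with -1.22 for PPDKB in non-elongating leaves on day 6, -2.09 for CIPK15 in elongating leaves on day 3, and -2.20 for ACO1 (OS09G0451000), the last enzyme of ethylene synthesis, in non-elongating leaves on day 3. Amy3D differed in non-elongating leaves on day 3 with adjusted p = 0.0028, also with a group of at most 3 counts in total. In elongating leaves on day 1 it was -4.19 for EXPB11 (OS02G0658800), -3.95 for EXPB4, -3.30 for EXPB3, -4.03 for EXPA2 (OS01G0823100) and -2.58 for EXPA4, all expansins. Among cellulose synthases it was -0.549 for CESA1 in non-elongating leaves on day 1, and -0.951 for CESA3 (OS07G0424400) and -0.995 for CESA8 (OS07G0208500) in elongating leaves on day 3. In chlorophyll breakdown it was -3.66 for SGR in elongating leaves on day 6, -1.48 for NYC1 in non-elongating leaves on day 1 and -2.09 for GDH2 in elongating leaves on day 3. RCCR1 (OS10G0389200), a reductase of chlorophyll breakdown, had -1.82 in elongating leaves on day 6, and CHLD (OS03G0811100), a subunit of magnesium chelatase, -0.703 there on day 1, both chosen after their values were seen.

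Further negative differences were -0.868 for CHLH, -1.39 for LHY and -1.39 for RCA in elongating leaves on day 1, -3.02 for NAC5 in non-elongating leaves on day 1 and -3.59 for CATA there on day 3. TIP2_2 had -1.08 in elongating leaves on day 3, and MCM2 (OS11G0484300), a helicase subunit of DNA replication, -2.14 in non-elongating leaves on day 6. The calls printed above for ADH2, Amy3D, ACO1, EIL1, ERF67, CESA1, RCCR1, GRF7, DREB1C and MCM2 were each lost under at least 1 of the alternatives.

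Of the lists, these differed in response by camera adjusted p. In non-elongating leaves the value was 0.0102, 1.17e-05, 0.000138, 0.0116 and 3.55e-05 for aquaporins, expansins, the Sub1 and group VII list, primary wall cellulose and senescence on day 1. On day 3 it was 0.0174, 0.0349, 0.00321, 0.000189 and 1.61e-07 for aquaporins, chlorophyll synthesis, the Sub1 and group VII list, reactive oxygen and senescence. On day 6 it was 0.0211, 0.000203 and 3.24e-05 for abscisic acid, the Sub1 and group VII list and senescence. In elongating leaves it was 1.47e-08, 6.96e-10, 0.0148, 0.0486, 6.96e-10, 0.000347 and 0.0148 for chlorophyll synthesis, expansins, the Sub1 and group VII list, growth-regulating factors, photosystems, primary wall cellulose and reactive oxygen on day 1. On day 3 it was 0.00685, 0.00738, 0.00055, 0.0224, 0.000491, 0.00982 and 0.00982 for aquaporins, expansins, the Sub1 and group VII list, photosystems, primary wall cellulose, reactive oxygen and senescence. On day 6 it was 0.0497, 0.00144 and 2.57e-06 for expansins, the Sub1 and group VII list and senescence. With an estimated correlation the calls of aquaporins on days 1 and 3, primary wall cellulose on day 1, chlorophyll synthesis, the Sub1 and group VII list and reactive oxygen on day 3 were lost in non-elongating leaves (adjusted p = 0.0722, 0.0804, 0.292, 0.453, 0.0542 and 0.0804 with an estimated correlation). In elongating leaves those of the Sub1 and group VII list, growth-regulating factors, photosystems, primary wall cellulose and reactive oxygen on day 1 (0.114, 0.114, 0.132, 0.128 and 0.197), of photosystems, primary wall cellulose and reactive oxygen on day 3 (0.517, 0.0954 and 0.201) and of expansins on day 6 (0.125) were lost.

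The response on day 1 scored larger in M202(Sub1) than in M202 in both leaf types. Sequencing depth and a few abundant genes are argued against as the whole cause. After thinning all libraries to 4873142 counts, the difference was 14.6 pooled SDs of the submerged libraries in non-elongating and 7.93 in elongating leaves. Without the 500 most abundant genes it was 15.6 and 7.07. These SDs leave out the spread at day 0. By a jackknife that includes it, the difference was 5.93 and 9.16 SEs after thinning and 5.79 and 7.47 without those genes. The 7.43 pooled SDs with RLE or upper-quartile factors do not test scaling, because those factors hardly differ in their effect on the score, but a shift of all genes by the whole range of the factors (0.404 log2 units) moved the score by at most 29.5% of the difference, which argues against scaling within that range as the whole cause. An axis drawn from one genotype favours it by construction (-0.0117 and -0.0585 for M202, 0.175 and 0.207 for M202(Sub1)). The genotype may set the size of the response on day 1, as a hypothesis found and tested on these data.

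The senescence and chlorophyll breakdown list was lower in M202(Sub1) in non-elongating leaves on days 1, 3 and 6. The largest camera adjusted p with RLE and upper-quartile factors, 1.4e-05, does not test scaling, because camera ranks the list against other genes and a shift common to all leaves the ranks alone. Tested on its own without scaling factors, which put the median of all genes at -0.102, -0.0741 and 0.156 log2 units, the list was lower on each day (largest fry adjusted p 2.12e-06), which argues against scaling as the whole cause. A poorer count of donor sequence against the reference would act at day 0 as well, and the list median there was -1.63% of the smallest median of the submerged days. Its sign depends on the scaling (0.00805 with TMM and -0.00614 with upper-quartile factors), so only its small size is read. A candidate explanation is the genotype itself, as a hypothesis found and tested on these data, and which gene of the carried sequence acts was not tested.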

How the results depend on the processing

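The fits with checked list members alone and with the axis of M202(Sub1) were tests chosen after seeing the data. Of 180 counts of genes under the 6 other settings 177 stayed within 1.5 times, as did 249 of 252 with 1 library left out, and no gene called in both a comparison and its alternative turned direction. In the fit of the groups compared alone the genotype count of non-elongating leaves was 386 on day 0 and 1336 on day 6, and the difference of responses on day 6 was 486 (the cause was not tested). The genotype count of elongating leaves on day 0 ranged from 517 without M202 replicate 1 to 1375 without M202 replicate 2, with 697 and 665 without replicates 1 and 3 of M202(Sub1). The lists had 189 calls, 101 with an estimated correlation, 386 with fry, which asks another question, and 112 with checked members only. In the simulated genotype comparison 17.9% of genes changed 1.5-fold were recovered. Only 200 of 20570 genes were changed there, and the adjusted threshold eases where more genes differ. The share therefore does not carry over to the real comparisons under water. In elongating leaves on day 1, for example, 1716 of the 4358 genes called between the genotypes differed at least 2-fold.

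The response size difference turned on the axis of M202 alone (-0.0117, -0.0809 and -0.112 on days 1, 3 and 6 in non-elongating and -0.0585, -0.0653 and -0.0856 in elongating leaves) and grew on that of M202(Sub1) alone (0.175, 0.133 and 0.133, and 0.207, 0.171 and 0.137). An axis from one genotype favours that genotype by construction. With a prior count of 0.5 the day 3 value of elongating leaves was 0.049, and the cause was not tested. With 1 library left out the range was 0.0741 to 0.104, 0.00891 to 0.043 and -0.00572 to 0.0248 in non-elongating leaves, and 0.0783 to 0.108, 0.0523 to 0.0752 and 0.0125 to 0.0399 in elongating leaves. Non-elongating leaves on day 6 turned to -0.00572 without M202 replicate 1 of day 0, and were also negative without M202 replicate 1 or 2 of day 6.

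For named genes, called or not, 9032 of 9276 tests under other settings and 10856 of 11424 with 1 library left out stayed on their side of the threshold. A call was lost in 118 and 459 of these tests, and none turned direction. A replicate block changed the counts by a factor of 0.967 to 1. The samples were not treated as paired by their numbers. Libraries with the same number in different groups deviated together with a mean correlation of 0.00129 over 360 pairs. Most of these pairs join different genotypes or days, so they say little about a pairing of leaf types. Between the 2 leaf types of one genotype and day the mean was 0.00743 over 24 pairs with the same number. With different numbers it was -0.00368 over 48 pairs. Of the 48 libraries 24 correlated best with their own number in the other leaf type, more than the 1 in 3 of unrelated numbers. A weak pairing is therefore not excluded.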

Other observations

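The tests of the stretches of neighbouring genes were chosen after the result was seen.

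Genes called in all 8 genotype comparisons in the same direction lay close together. Of the 190 genes 114 lay in 13 stretches of 50 tested genes with at least 5 of them, 12 on chromosome 6, 35 on chromosome 9, 20 on chromosome 11 and 47 on chromosome 12. Random placement is argued against by a permutation test, because the highest of 10000 shuffles put 12 genes into such stretches (permutation p = 0.0001, the smallest they can give). The stretches may be sequence of the donor of the Sub1 locus, or differences between the seed stocks, and no genotype calls were used here to decide it. Donor sequence counted less well against the reference would lower counts in M202(Sub1), and 78.1% of the genes in the stretches were lower (exact 95% interval 69.4 to 85.3%), against 57.9% of the 76 genes outside them. Lower counting alone would not raise the other 21.9% (14.7 to 30.6%), which were higher.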
